A study of Caenorhabditis elegans with 4 samples.

How the data were processed

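Whole N2 hermaphrodites were sampled in 4 libraries, 2 from worms on OP50 and 2 from the group labelled as fed OP50 with MH-1. Per the labels, total RNA was extracted with a lipid tissue kit from about 200 worms per group, poly(A) RNA was selected with beads, and libraries were made with a stranded mRNA kit. The labels disagree in 2 places. The treatment label names OP50 together with MH-1 while the treatment protocol names OP50 or MH-1, and the series title speaks of larval stages while the protocol has worms of day 1 placed on the diet for 2 days. The diet reading was left open. On the stage, transcripts of yolk and of oocytes were abundant in the OP50 group (*vit-2* 10830 CPM, *cpg-2* 2785 CPM), as in egg-producing adults. These transcripts do not exclude that larvae were also present. The worms are described here by the protocol, and the label of larval stages was not used. Groups and replicate numbers were taken from the sample labels.

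The authors deposited whole-number read counts per gene, 1 file per library, with 46926 genes and the exon coordinates, length and annotation terms of each. Per the submitters' processing notes, the tools were Trim Galore 0.6.7, Trimmomatic 0.39, cutadapt 3.7, STAR 2.7.10a and featureCounts 2.0.1, with the builds ce11 and WBcel235 named. The roles and order of these tools, the strand setting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. Depending on those settings, counts of near-identical genes (heat shock, major sperm protein, vitellogenin and *pud* genes) and of genes that overlap on opposite strands can hold reads of their partners. All 46926 deposited gene spans equal those of the Ensembl release 115 annotation of WBcel235, which gave biotypes, and coordinates are on that build. Exon overlaps were taken from the deposited exon coordinates. Of the 85 genes the rule below names, none shares over 10% of its exonic bases with a gene on the same strand and 2 do with a gene on the opposite strand (*col-158* 14.2% and *sod-3* 10.1%). GC content was not analysed here.

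Total counts were 28320527 and 14657033 in the OP50 libraries and 40297219 and 15255225 in the MH-1 libraries. The 10 most abundant genes took 5.07% to 6.03% of the counts, and ribosomal RNA genes 0.123% to 0.221%. The libraries carry no molecular identifiers that were used here, so the floors per library cover counting error only. Replicates differed by more than sampling noise (chi-square per degree of freedom of 7.43 for OP50 and 11.0 for MH-1), so none was counted as a repeat of another. Nothing in the labels says that replicates came from separate cultures of worms, and p-values then measure only the spread between these samples, which may be technical.

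From the deposited counts, genes were filtered with filterByExpr (default settings), normalized by TMM (factors from 0.989 to 1.01) and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest, group as the only term). P-values were adjusted by the Benjamini-Hochberg method over the 13672 tested genes, and genes with an adjusted p under 0.05 are called. The common biological coefficient of variation was 8.1%. CPM values are TMM-normalized, group values are means with the SD of 2 libraries, and log2 fold changes come from the fitted model. Their SE was calculated back from the test, as the absolute log2 fold change divided by the square root of the F statistic. Intervals are built from this SE. Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) where at least 4 members were tested, adjusted over the 42 lists, and again with an estimated correlation and with fry. List names were matched to the gene names in the files, and 12 names had no match.

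The design, the 42 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names, first, the 8 largest increases and the 8 largest decreases among called genes that reach 5 CPM in the higher group and whose replicates do not overlap. It names next, for each list that camera calls or that holds at least 3 called genes, up to 4 called members with the smallest adjusted p. It also names 14 genes whatever their outcome (*acdh-1*, *vit-2*, *sod-3*, *mtl-1*, *gst-4*, *lys-7*, *sysm-1*, *hsp-4*, *hsp-6*, *hsp-16.2*, *fat-7*, *acs-2*, *daf-16*, *skn-1*) and the most abundant member of each list without a call. Genes outside the rule are said to be named after their values were seen.

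The gene test was checked on simulated counts drawn with the real means, library sizes and dispersion trend, with 200 changed genes among 13452 tested for the comparison of MH-1 with OP50. It recovered 38.8% of the 67 genes changed by 1.5-fold, 79.1% of the 67 changed by 2-fold and 95.5% of the 66 changed by 4-fold, and 3 unchanged genes were called (2.1% of the calls). Changes under 1.5-fold are therefore often missed with 2 libraries per group. The list test called 0 of 42 unchanged lists and called a list of 20 genes raised by 1.4-fold. Genes were drawn independently in this simulation, so it does not cover lists whose members vary together. In the real lists the estimated correlation reached 0.952 (vitellogenins).

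Alternatives fixed in advance were DESeq2 1.42.0, limma-voom, median-of-ratios and total-count scaling, no filter and a filter of 1 CPM in 2 libraries, non-robust dispersion, the replicate number as a block, each library left out, a test against a fold of 1.5 and an adjusted p under 0.01. Added after seeing the data were the removal of a gene length trend (a loess with span 0.5 of each library's deviation on log2 length, on log CPM with a prior count of 2, used as an offset), thinning to equal depth, a hypergeometric test of annotation terms of 5 to 500 genes over the 9795 tested genes that carry terms in the files, and a permutation count of called neighbouring genes. Intervals are 95%. Tables were handled with Python 3.11.15 and pandas 2.3.3 and figures drawn with matplotlib 3.10.9.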

Results

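The data are poly(A) RNA-seq gene counts from whole wild-type (Bristol N2) *Caenorhabditis elegans* hermaphrodites. The comparison asks which transcripts change when the worms feed on MH-1, a *Lactiplantibacillus* isolate (a genus of lactic acid bacteria), instead of the laboratory food *Escherichia coli* OP50 alone. Worms spent 2 days on their diet from day 1 of age, and about 200 were collected per group. The sample labels name the treated diet as OP50 with MH-1, whereas the labels' protocol names MH-1 in place of OP50, so that group is called the MH-1 group here without settling whether OP50 was present. The 4 libraries form 2 groups of 2. The OP50 libraries held 28320527 (replicate 1) and 14657033 (replicate 2) gene counts, and the MH-1 libraries 40297219 and 15255225. Between 17790 and 19866 genes had at least 1 count in a library, and 3 counts corresponded to between 0.0744 and 0.205 CPM (counts scaled to library size). That floor covers counting error only.

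Worms of the MH-1 group carried far more mRNA of *fat-7*, which encodes a stearoyl-CoA desaturase that makes oleic acid. Its level was 10.2 ± 0.875 CPM on OP50 and 99.5 ± 1.96 CPM on MH-1 (SD, n = 2 each), a 9.66-fold rise. Genes of lysosomal and gut proteases (*cpr-1*, *asp-8*) and of a lysozyme (*lys-4*) rose as well. Some inducible heat shock genes (*hsp-70*, *hsp-16.2*), cuticle collagens (*col-81*), moulting genes (*noah-1*) and several infection response genes (*sysm-1*) fell. Of 13672 genes tested, 74 were higher and 114 lower on MH-1 by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, and 1783 passed an unadjusted p of 0.05. At least a 2-fold difference was seen for 34 of the higher and 35 of the lower genes, and the median fold of the called genes was 1.68. All 188 called genes had replicates that did not overlap between the groups, a property of 44.3% of tested genes against 33.3% by chance for 2 libraries against 2.

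Leaving out a library also takes away its depth, and the deepest were MH-1 replicate 1 (40297219 counts) and OP50 replicate 1 (28320527 counts). For calls lost without them, loss of depth cannot be told apart from the weight of that single library. The number of calls changed with the library left out. It was 62 (31 higher, 31 lower) without MH-1 replicate 1, 109 (50 higher, 59 lower) without OP50 replicate 1, 268 (96 higher, 172 lower) without OP50 replicate 2 and 291 (72 higher, 219 lower) without MH-1 replicate 2. In all 4 of these fits 44 of the calls remained, 26 of them higher and 18 lower. Among the genes named by the rule, calls were lost 45 times in these fits, each time with the sign kept, and the log2 fold change shrank by over 1.5 times in 1 of the 45 (*ugt-44*).

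**Figure D1:**
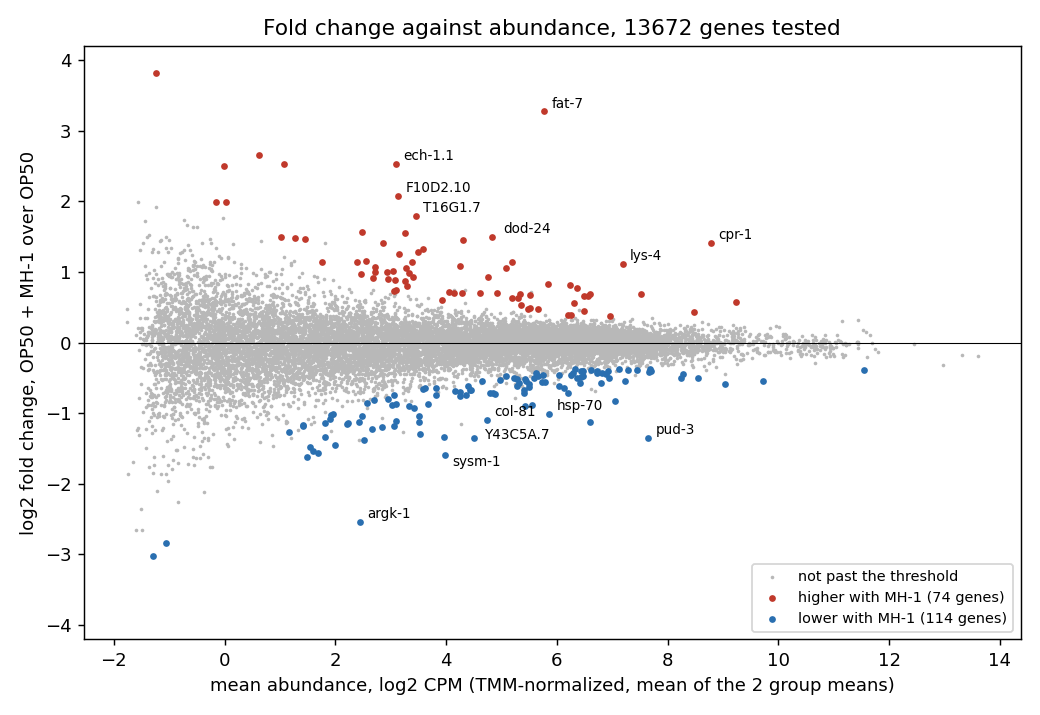
Log2 fold change of OP50 + MH-1 over OP50 (vertical axis) against mean abundance in log2 CPM (horizontal axis) for the 13672 tested genes, with 74 called higher in red, 114 called lower in blue and the rest in grey. The gene *fat-7* stands at 3.27, above other genes of its abundance, and *argk-1* at -2.53.

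Among genes that reached 5 CPM in the group where they were higher, the largest rises after *fat-7* (chromosome V, 7151353 to 7153146, minus strand, WBcel235; log2 fold change 3.27 ± 0.12 SE, edgeR adjusted p = 6.81e-12) were those of *ech-1.1*, *F10D2.10* and *T16G1.7*. The enoyl-CoA hydratase gene *ech-1.1* went from 2.5 ± 0.0487 to 14.6 ± 2.28 CPM (SD, n = 2; log2 2.53 ± 0.20 SE, edgeR adjusted p = 1.05e-06). The gene *F10D2.10* lies 1356 bases from *fat-7* on the same strand and rose by 2.08 ± 0.18 on the log2 scale (SE, edgeR adjusted p = 2.41e-06). The other rises among the 8 largest were *T16G1.7* (1.80), the aspartic protease gene *asp-8* (1.57), the cytochrome P450 gene *cyp-13B1* (1.55), *dod-24* (1.5) and *C50B6.7* (1.45), with edgeR adjusted p between 2.41e-06 and 5.69e-04.

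The largest fall was that of *argk-1*, an arginine kinase family gene on chromosome V (16103894 to 16105952), from 9.26 ± 0.662 to 1.69 ± 0.475 CPM (SD, n = 2; log2 -2.53 ± 0.23 SE, edgeR adjusted p = 4.57e-06). Its neighbour *cth-1*, a cystathionine gamma-lyase gene 1143 bases away, fell from 22.2 ± 4.62 to 8.94 ± 0.567 CPM (log2 -1.34 ± 0.16 SE, edgeR adjusted p = 1.39e-04). The abundant *pud-3* fell from 288.6 ± 1.09 to 113.5 ± 7.05 CPM (log2 -1.35 ± 0.08 SE, edgeR adjusted p = 4.04e-08). The other members of the 8 largest falls were *sysm-1* (log2 -1.59), *ora-1* (-1.45), the glucuronosyltransferase gene *ugt-44* (-1.38), *Y43C5A.7* (-1.34) and *F58G6.9* (-1.30). Without MH-1 replicate 1, *ora-1* missed the threshold with a larger fall (log2 -1.61, edgeR adjusted p = 0.0619) and *ugt-44* with a smaller one (-0.84, 0.366). *ugt-44* also missed it with the libraries thinned to equal depth (0.0627).

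**Figure D2:**
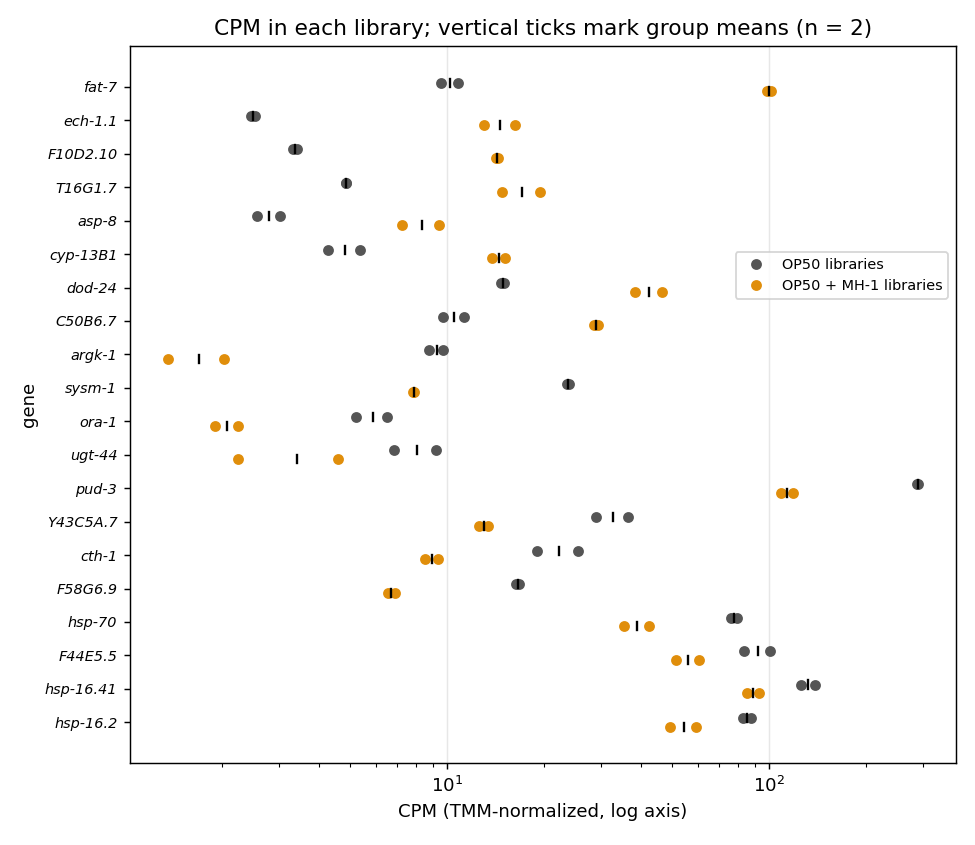
CPM in each of the 4 libraries on a log axis (grey, OP50; orange, OP50 + MH-1) for the 16 genes with the largest changes and 4 heat shock genes, with black ticks at the group means. The libraries of the 2 groups do not overlap for any of the 20 genes.

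Fatty acid genes changed in both directions. Of 18 tested genes of fatty acid synthesis and desaturation, 2 rose, 1 fell and 15 did not pass. Adjusted over the list alone 9 passed, 4 higher and 5 lower. The called rises were *fat-7* and *fat-3*, a delta-6 desaturase gene (74.2 ± 6.33 to 119.3 ± 10.9 CPM, SD, n = 2, log2 0.69 ± 0.10 SE, edgeR adjusted p = 6.15e-04). The called fall was *dgat-2*, a diacylglycerol acyltransferase gene (log2 -1.11 ± 0.20 SE, edgeR adjusted p = 0.006). The list was called higher by camera (adjusted p = 0.00726; adjusted p = 0.744 with an estimated correlation), although its median log2 fold change was -0.09 and its mean 0.09. The median was -0.04 without OP50 replicate 1, -0.01 without MH-1 replicate 1 and -0.14 without OP50 replicate 2. The list's call was lost without OP50 replicate 2 (adjusted p = 0.18), without MH-1 replicate 2 (adjusted p = 0.672) and with the gene length trend described further on removed (adjusted p = 0.799), and the direction turned with limma-voom (adjusted p = 0.911).

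Of 22 tested genes of lipolysis and fatty acid oxidation, 4 rose, 2 fell and 16 did not pass. Adjusted over the list alone 7 passed, 4 higher and 3 lower. *ech-1.1*, the carnitine palmitoyltransferase gene *cpt-5* (log2 1.32 ± 0.20 SE), the lipase gene *lipl-2* (1.26 ± 0.21) and the acyl-CoA synthetase gene *acs-2* (0.37 ± 0.08) rose, with edgeR adjusted p between 1.05e-06 and 0.0267. The lipase gene *lipl-5* fell from 236.3 ± 2.24 to 179.6 ± 14.7 CPM (log2 -0.40 ± 0.08 SE, edgeR adjusted p = 0.0194), and *acdh-2*, named after its value was seen, fell by 0.37 on the log2 scale (edgeR adjusted p = 0.0493). The *acdh-2* call was lost in all 4 fits that leave out a library (edgeR adjusted p from 0.108 to 0.255), with limma-voom (0.0629), other scaling (0.0512 and 0.0743), non-robust dispersion (0.0619), the length trend removed (0.0711) and thinning (0.0737). The list was not called by camera (adjusted p = 0.0818), its mean log2 fold change was 0.16 and its median -0.03, between -0.079 and 0.015 with a library left out. Without MH-1 replicate 1, *dgat-2*, *lipl-2*, *lipl-5* and *acs-2* missed the threshold (edgeR adjusted p = 0.229, 0.0949, 0.307 and 0.185). Without OP50 replicate 1, *dgat-2* and *acs-2* missed it (edgeR adjusted p = 0.0583 and 0.213), and *acs-2* also without MH-1 replicate 2 (edgeR adjusted p = 0.0778) and with thinning (0.0606).

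Several genes of digestive enzymes rose. Of 20 tested digestive protease genes (cathepsin B, L and Z and aspartic proteases), 4 rose, none fell and 16 did not pass, and 6 passed when adjusted over the list alone. The cathepsin B genes *cpr-1* (240.9 ± 6.06 to 640.5 ± 123 CPM, SD, n = 2; log2 1.41 ± 0.11 SE, edgeR adjusted p = 2.1e-06) and *cpr-4* (log2 0.68 ± 0.09 SE, edgeR adjusted p = 4.79e-04) and the aspartic protease genes *asp-8* and *asp-2* (log2 0.44 ± 0.09 SE, edgeR adjusted p = 0.0193) were the ones that rose. Camera called the list higher (adjusted p = 2.16e-08; adjusted p = 0.602 with an estimated correlation). Without MH-1 replicate 2, *asp-2* missed the threshold (edgeR adjusted p = 0.118).

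Of 10 tested lysozyme genes, 2 rose and 8 did not pass, and 6 passed when adjusted over the list alone, 4 higher and 2 lower. *lys-4* rose from 92.7 ± 6.94 to 200.2 ± 1.48 CPM (SD, n = 2; log2 1.11 ± 0.09 SE, edgeR adjusted p = 9.24e-07), and its neighbour *lys-5* from 1.11 ± 0.263 to 2.96 ± 0.582 CPM (log2 1.49 ± 0.31 SE, edgeR adjusted p = 0.0172). *lys-7* stood at 82.7 ± 2.43 and 79.4 ± 17.2 CPM and did not pass (edgeR adjusted p = 0.845). The list was called higher by camera (adjusted p = 9.08e-04; adjusted p = 0.49 with an estimated correlation). The *lys-5* call was lost without OP50 replicate 1 (edgeR adjusted p = 0.221), without MH-1 replicate 1 (0.486), with DESeq2 (0.147) and with thinning (0.0699). The list's call was lost once the gene length trend described further on was removed (camera adjusted p = 0.182). That list test ran on log CPM instead of counts, so the loss may not come from length alone. Both genes stayed called, and the list's median log2 fold change was 0.19 against 0.23. That median was 0.70 without OP50 replicate 2 and 0.44 without MH-1 replicate 2. Of 15 tested markers of the intestine, where these enzymes are made, 1 fell (*mtl-2*, a metallothionein gene, log2 -0.57 ± 0.09 SE, edgeR adjusted p = 0.0015) and 14 did not pass, and 3 passed when adjusted over the list alone. Camera called the list lower (adjusted p = 0.00108; adjusted p = 0.744 with an estimated correlation; 0.106 without MH-1 replicate 1). Its median log2 fold change was -0.16, and -0.08 without MH-1 replicate 1 and -0.28 without OP50 replicate 2.

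Immune genes moved in both directions. Of 16 tested infection response genes, 2 rose, 6 fell and 8 did not pass. Adjusted over the list alone 12 passed, 4 higher and 8 lower. *sysm-1*, a reporter gene of the p38 PMK-1 pathway also known as T24B8.5, fell from 23.7 ± 0.179 to 7.87 ± 0.0431 CPM (SD, n = 2; log2 -1.59 ± 0.14 SE, edgeR adjusted p = 3.54e-06), and *K08D8.5* fell by 1.22 on the log2 scale (edgeR adjusted p = 0.00158). In the same list *dod-24* rose from 14.9 ± 0.199 to 42.3 ± 5.65 CPM (edgeR adjusted p = 2.41e-06) and *irg-3* from 6.35 ± 1.2 to 13 ± 0.64 CPM (edgeR adjusted p = 0.0037). The list was called lower by camera (adjusted p = 0.00283; adjusted p = 0.602 with an estimated correlation), and fry's mixed test, which counts changes in either direction, gave an adjusted p of 0.011. *K08D8.5* and *irg-3* missed the threshold without MH-1 replicate 1 (edgeR adjusted p = 0.0653 and 0.0599), *irg-3* also without OP50 replicate 1 (0.0545). The list's call was lost without OP50 replicate 2 (camera adjusted p = 0.125). It had 1 rise and 1 fall without MH-1 replicate 1, 3 and 3 without OP50 replicate 2, 1 and 4 without OP50 replicate 1 and 3 and 5 without MH-1 replicate 2.

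Of 38 tested epidermal antimicrobial peptide genes, 4 fell, none rose and 34 did not pass. Adjusted over the list alone 13 passed, 1 higher and 12 lower. The 4 called genes were *nlp-34* (log2 -1.13 ± 0.16 SE, edgeR adjusted p = 6.82e-04), *fip-6* (-1.03), *cnc-6* (-1.14) and *nlp-24* (-0.43). The median of the list was -0.25 (camera adjusted p = 6.88e-07, and 0.49 with an estimated correlation). Without MH-1 replicate 1 only *nlp-34* of these 4 passed, and the list's median was -0.38. *fip-6* missed the threshold in each of the 4 fits that leave out a library (edgeR adjusted p from 0.0515 to 0.188), *cnc-6* and *nlp-24* did so in 3 of them (0.078 to 0.402 and 0.12 to 0.335), and DESeq2 did not call *fip-6* or *cnc-6* (0.132 and 0.122). Thinning also ended the *cnc-6* call (0.0535). Of 88 tested C-type lectin genes, 4 rose, 4 fell and 80 did not pass. Adjusted over the list alone 14 passed, 7 higher and 7 lower. *clec-218* (log2 1.14), *clec-5* (1.08) and *clec-80* (1) rose and *clec-186* (-0.63) fell, with edgeR adjusted p between 3.8e-04 and 0.017. The lectin list was not called by camera (adjusted p = 0.591), and fry's mixed test gave an adjusted p of 0.0022. That mixed test called 19 of the 42 lists, among them neuron markers (adjusted p = 0.0203), which held no called gene. *clec-186* missed the threshold without MH-1 replicate 1 or OP50 replicate 2 (edgeR adjusted p = 0.217 and 0.141) and *clec-80* without OP50 replicate 2 or MH-1 replicate 2 (0.0557 and 0.0774). The lectins had 3 rises and 0 falls without MH-1 replicate 1, 4 and 1 without OP50 replicate 1, 2 and 1 without OP50 replicate 2 and 3 and 3 without MH-1 replicate 2.

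Some inducible heat shock genes fell. Of 15 tested genes of the heat shock response, 5 fell, none rose and 10 did not pass, and 6 passed when adjusted over the list alone. *hsp-70* (chromosome I, 9320325 to 9322519), an inducible member of the Hsp70 family, fell from 77.5 ± 2.45 to 38.8 ± 4.85 CPM (SD, n = 2; log2 -1.01 ± 0.11 SE, edgeR adjusted p = 2.74e-05). The Hsp70 family gene *F44E5.5* (-0.72 ± 0.11), with its near-identical neighbour *F44E5.4* (-0.88 ± 0.15), and the small heat shock genes *hsp-16.2* (-0.65 ± 0.10) and *hsp-16.41* (-0.57 ± 0.09) fell with edgeR adjusted p between 0.00139 and 0.00646. *F44E5.4* was named after its value was seen. As a list they were called lower by camera (adjusted p = 5.21e-12; adjusted p = 0.49 with an estimated correlation), with a median log2 fold change of -0.65. That median was -0.16 without OP50 replicate 1 and between -0.47 and -0.80 in the other 3 fits that leave out a library, and at least 5 genes were called lower in each of the 4. The libraries of a group differed in these genes too, since the list's median deviation from the mean of the 4 libraries was 0.37 and 0.08 (log2) in the OP50 libraries and -0.12 and -0.38 in the MH-1 libraries. Reads of near-identical copies may be split unevenly among *F44E5.4*, *F44E5.5* and the *hsp-16* genes, so single values in this family are uncertain.

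Markers of other protein stress pathways did not pass the test. In the endoplasmic reticulum stress list none of 19 tested genes passed, with *hsp-4* at 387.9 ± 21.8 and 381.5 ± 2.92 CPM (SD, n = 2; edgeR adjusted p = 0.932) and *crt-1* at 1031 ± 25.4 and 940.1 ± 41.9 CPM (0.525). In the mitochondrial stress list none of 13 passed, with *hsp-6* at 470.5 ± 49.3 and 386.6 ± 21 CPM (edgeR adjusted p = 0.157), although 4 members had an unadjusted p under 0.05 and DESeq2 called 1.

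Some genes of the cuticle fell. Of 96 tested cuticle collagen genes, 8 fell, none rose and 88 did not pass, and 20 passed when adjusted over the list alone. *col-81* fell from 36.4 ± 5.04 to 16.8 ± 1.37 CPM (SD, n = 2; log2 -1.09 ± 0.13 SE, edgeR adjusted p = 1.39e-04), *col-98* from 441.7 ± 51.1 to 312.4 ± 3.49 CPM (log2 -0.50 ± 0.09 SE, edgeR adjusted p = 0.006), and *col-129* and *col-158* by 0.72 and 1.48 on the log2 scale (edgeR adjusted p = 0.00302 and 0.00454). The exons of *col-158* overlap those of *nphp-4* on the opposite strand over 14.2% of their bases. Camera called the collagen list lower (adjusted p = 8.91e-06; adjusted p = 0.602 with an estimated correlation). The 10 most abundant cuticle collagens, none of them called, had a median log2 fold change of -0.12, close to the -0.13 of the whole list, which was -0.21 without OP50 replicate 2 and -0.24 without MH-1 replicate 2. Without MH-1 replicate 1 the list had 4 falls, and *col-98* and *col-158* missed the threshold there (edgeR adjusted p = 0.135 and 0.148) and without OP50 replicate 1 (0.0806 and 0.0507), where the list had 5 falls and 1 rise.

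Of 23 tested moulting genes, 4 fell, none rose and 19 did not pass, and 5 passed when adjusted over the list alone. They were *noah-1* and *noah-2*, which encode apical matrix proteins (log2 -0.61 ± 0.09 and -0.62 ± 0.11 SE, edgeR adjusted p = 0.00143 and 0.006), the fibrillin-related gene *fbn-1* (-0.72 ± 0.12, 0.0027) and the protease inhibitor gene *mlt-11* (-0.75 ± 0.15, 0.0115). The list was called lower by camera (adjusted p = 9.41e-05; adjusted p = 0.49 with an estimated correlation). With the gene length trend removed, *fbn-1* stood at -0.48 ± 0.11 and *mlt-11* at -0.50 ± 0.16 and neither passed (edgeR adjusted p = 0.0527 and 0.192), while *noah-1* and *noah-2* did (0.0113 and 0.0141). Without MH-1 replicate 1, *fbn-1* and *noah-2* missed the threshold (edgeR adjusted p = 0.0578 and 0.0619), as *mlt-11* did without OP50 replicate 1 (0.0529). Hypodermis markers mark the tissue that makes the cuticle, and some of them are cuticle collagens. They included 1 fall among 15 tested genes (*vab-10*, log2 -0.39 ± 0.09 SE, edgeR adjusted p = 0.0344), and 3 passed when adjusted over the list alone. Their median was -0.26 (camera adjusted p = 0.0437, and 0.602 with an estimated correlation). The *vab-10* value was -0.05 with the length trend removed (edgeR adjusted p = 0.821) and its call was also lost without OP50 replicate 1 (0.155) or MH-1 replicate 1 (0.509), with non-robust dispersion (0.0597) and with thinning (0.0636). The hypodermis call was lost without OP50 replicate 1 (median -0.04) and without MH-1 replicate 2 (median -0.18). It was also lost with the length trend removed (camera adjusted p = 0.229, median -0.17) and with non-robust dispersion (camera adjusted p = 0.0506, median -0.26). Of 11 other genes of the late embryonic cuticle and of hatching, listed after the data were seen, 9 lay below 0 with a median log2 fold change of -0.40, and 8 with a median of -0.23 once the length trend was removed. None of the 11 was called by edgeR, DESeq2 or limma-voom, and 6 had an unadjusted p under 0.05 in edgeR.

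**Figure D3:**
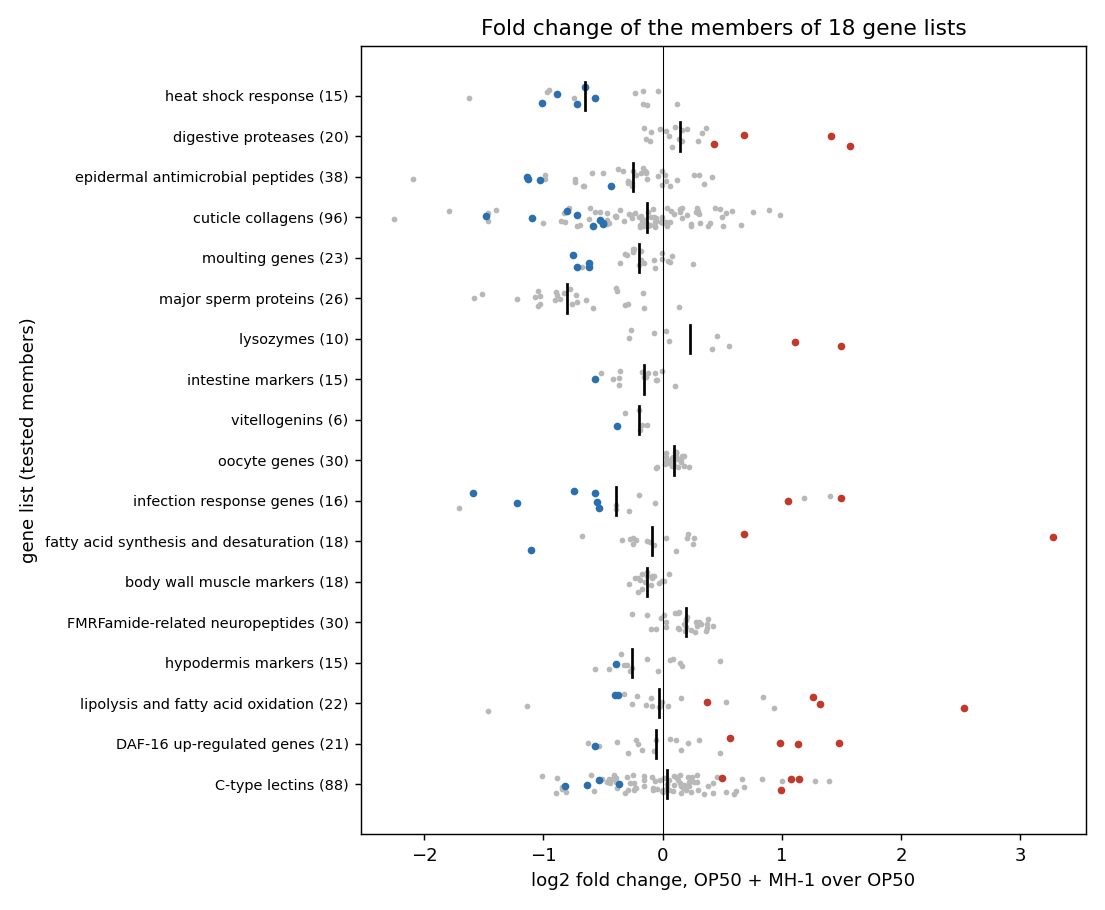
Log2 fold change (OP50 + MH-1 over OP50, horizontal axis) of every tested member of the 18 lists that camera called or that held at least 3 called genes, with the number of tested members in brackets, called genes in red (higher) or blue (lower), the others in grey and a black bar at each list's median. Called heat shock, collagen and moulting genes all lie below 0, called lysozyme and digestive protease genes above 0, and infection response genes on both sides.

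Genes known to be raised by DAF-16, the FOXO factor of insulin signalling, were mixed. Of 21 tested, 4 rose, 1 fell and 16 did not pass. Adjusted over the list alone 9 passed, 6 higher and 3 lower. *dod-3* rose from 23 ± 3.44 to 49.7 ± 8.85 CPM (SD, n = 2; log2 1.14 ± 0.14 SE, edgeR adjusted p = 1.39e-04), and the small heat shock genes *hsp-12.3* (log2 0.99 ± 0.18 SE) and *hsp-12.6* (1.48 ± 0.29) and the LEA protein gene *lea-1* (0.57 ± 0.11, named after its value was seen) rose with edgeR adjusted p between 0.00646 and 0.0131. The called fall was *mtl-2*. The standard reporters did not pass: *sod-3* was at 4.33 ± 0.501 and 2.96 ± 0.152 CPM (edgeR adjusted p = 0.277), *mtl-1* at 21.7 ± 1.55 and 19 ± 2.8 CPM (0.557), and *daf-16* itself at 126.7 ± 3.83 and 121.9 ± 4.07 CPM (0.803). The list was not called by camera (adjusted p = 0.154), with a mean of 0.09 and a median of -0.06, between -0.093 and 0.119 with a library left out. *hsp-12.3* and *hsp-12.6* missed the threshold without OP50 replicate 1 (edgeR adjusted p = 0.141 and 0.213) and without MH-1 replicate 1 (0.155 and 0.168), *hsp-12.6* with DESeq2 (0.0757) and *lea-1* without MH-1 replicate 2 (0.0806). Of 9 genes known to be lowered by DAF-16, 1 rose (*dod-24*), 1 fell (*dod-19*, log2 -0.58, edgeR adjusted p = 0.0103, named after its value was seen) and 7 did not pass. Adjusted over the list alone 4 passed, 1 higher and 3 lower, and camera did not call the list (adjusted p = 0.97). The *dod-19* call was lost without OP50 replicate 1 (0.0806) and without MH-1 replicate 1 (0.177).

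Few detoxification genes passed the test. Among 22 tested targets of the oxidative stress factor SKN-1, 1 rose (*gst-10*, log2 0.48, edgeR adjusted p = 0.0246, named after its value was seen). Adjusted over the list alone 4 passed, 2 higher and 2 lower. The gene *gst-10* was also the 1 called higher among 40 glutathione S-transferases, of which 3 passed when adjusted over the list alone, 2 higher and 1 lower. The *gst-10* call was lost without OP50 replicate 1 (edgeR adjusted p = 0.115), OP50 replicate 2 (0.105) or MH-1 replicate 1 (0.202) and with the length trend removed (0.0506). *gst-4* was at 27.7 ± 3.40 and 32.6 ± 2.60 CPM (SD, n = 2; edgeR adjusted p = 0.434) and *skn-1* at 151.0 ± 5.02 and 136.8 ± 9.11 CPM (0.476). Among 55 cytochrome P450 genes, 1 rose (*cyp-13B1*), which was also the 1 that passed when adjusted over the list alone. Among 58 glucuronosyltransferase genes, *ugt-44* fell and the weakly expressed *ugt-15* (0.0685 to 0.777 CPM, edgeR adjusted p = 0.0423, named after its value was seen) rose. Adjusted over the list alone 9 passed, 2 higher and 7 lower. The list's median log2 fold change was -0.16, and -0.04 without OP50 replicate 1 and -0.24 without MH-1 replicate 2. The *ugt-15* call was lost without OP50 replicate 1 (log2 2.39 against 3.82, edgeR adjusted p = 0.651), MH-1 replicate 1 (0.445) or MH-1 replicate 2 (0.136), with non-robust dispersion (0.0547), the length trend removed (0.0537) and thinning (0.0858). DESeq2 gave *ugt-15* no adjusted p, and a filter of 1 CPM left it out. Among 16 metal homeostasis genes, *mtl-2* fell and *hrg-7* rose (log2 0.64, edgeR adjusted p = 0.0103, 0.0536 without MH-1 replicate 2, named after its value was seen), with 4 passing when adjusted over the list alone. Camera called none of these 5 lists (adjusted p from 0.104 to 0.313).

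Few reproductive genes passed the test. Vitellogenins, the yolk protein genes, included 1 fall among 6 tested (*vit-1*, 3379 ± 0.411 to 2588 ± 193 CPM, SD, n = 2; log2 -0.38 ± 0.09 SE, edgeR adjusted p = 0.0415), with 2 passing when adjusted over the list alone and a median of -0.20 (camera adjusted p = 0.00108; adjusted p = 0.744 with an estimated correlation). *vit-2* was at 10830 ± 767 and 9602 ± 1261 CPM (edgeR adjusted p = 0.506), and reads of the near-identical vitellogenin genes may be shared. The *vit-1* call and the list's call were both lost without MH-1 replicate 1 (edgeR adjusted p = 0.342, camera adjusted p = 0.106) and with the length trend removed (0.215 and 0.349), and *vit-1* also without OP50 replicate 1 or 2 (0.203 and 0.115), with non-robust dispersion (0.0576) and with thinning (0.0606). The list's median was -0.09 without MH-1 replicate 1 and -0.35 without MH-1 replicate 2. With the length trend removed it was -0.05, and *vit-1* stood at -0.24 ± 0.08 (log2, SE). Oocyte genes had no call among 30, but 28 of them lay above 0, with a median of 0.10 (camera adjusted p = 0.002; adjusted p = 0.49 with an estimated correlation), and the most abundant, *cpg-2*, was at 2785 ± 159 and 3153 ± 105 CPM (edgeR adjusted p = 0.416). Major sperm protein genes had no call among 26 and a median of -0.80 (camera adjusted p = 3.17e-04; adjusted p = 0.744 with an estimated correlation). Their list median lay 0.76 (log2) above the mean of the 4 libraries in OP50 replicate 1 and below it in the other 3, and without that library the direction of the list turned (median 0.06, camera adjusted p = 0.643). The median was -0.49 without MH-1 replicate 1. The most abundant of them, *msp-31*, was at 3.96 ± 0.861 and 4.60 ± 1.15 CPM, and reads of these near-identical genes may be shared.

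Body wall muscle markers (18 tested, median -0.13, camera adjusted p = 0.00845; adjusted p = 0.744 with an estimated correlation) and FMRFamide-related neuropeptide genes (30 tested, median 0.19, camera adjusted p = 0.00885; adjusted p = 0.543 with an estimated correlation) were called as lists without any called member. Both calls were lost without MH-1 replicate 1 (medians -0.07 and 0.15) and with the length trend removed (camera adjusted p = 0.414 and 0.0659, medians -0.04 and 0.13). The FMRFamide call was also lost without OP50 replicate 1 (median 0.15). The most abundant members were *pat-10* (1158 ± 82.4 and 1088 ± 44.8 CPM, SD, n = 2) and *flp-6* (55.7 ± 4.96 and 52.1 ± 0.00337 CPM). Together, the 22 lists without a call by edgeR held 519 tested genes, of which 51 had an unadjusted p under 0.05, DESeq2 called 2 and limma-voom called 0. They include the propionate shunt (5 tested), whose vitamin B12-responsive gene *acdh-1* was at 911.4 ± 6.73 and 961.0 ± 44.4 CPM (edgeR adjusted p = 0.74), and the methionine cycle with other B12-dependent enzymes (16 tested), where *ahcy-1* was at 1166 ± 49.4 and 1171 ± 92.0 CPM (0.985). They also include oxidative phosphorylation (44 tested, *atp-1* 0.893), cytosolic ribosomal proteins (80, *rpl-36* 0.82), autophagy and lysosome genes (27, *lgg-1* 0.439), the intracellular pathogen response (23, *drh-1* 0.898), chitinase-like genes (9, *cht-1* 0.383), insulin-like peptides (21, *ins-17* 0.697), the hypoxia and hydrogen sulfide response (13, *hif-1* 0.878) and histones (37, *his-72* 0.786), where each value is the edgeR adjusted p of the most abundant member. The remaining lists without a call were other sperm genes (20, *spe-44* 0.871), germline genes (26, *cgh-1* 0.399), early zygotic genes (23, *pal-1* 0.538), pharynx markers (16, *phat-7* 0.997), neuron markers (19, *snb-1* 0.974) and male-enriched genes (4, *xol-1* 0.43).

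Camera called 15 of the 42 lists, 5 higher and 10 lower. None of the 15 calls held with an estimated correlation (smallest adjusted p = 0.49, with 2 lists at an unadjusted p under 0.05) or with fry's directional test (smallest adjusted p = 0.0628, with 8 lists at an unadjusted p under 0.05). Heat shock, epidermal antimicrobial peptide, cuticle collagen, moulting, digestive protease, lysozyme and oocyte genes were the 7 lists that camera called in all 4 fits that leave out a library.

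Fold changes followed gene length. Across genes, which are not independent replicates, Spearman's correlation between log2 fold change and gene length was -0.22, and it was -0.43 over the 5428 genes above 32 CPM. Over those genes the correlation of a library's deviation with length was 0.33 and 0.29 in the OP50 libraries. It was -0.53 in MH-1 replicate 1, the most deeply sequenced library, and 0.08 in MH-1 replicate 2. Deviations are taken from the mean of the 4 libraries, so part of the OP50 rise mirrors the fall in MH-1 replicate 1. Of the 114 lower calls, 39 were in the longest of 5 equal parts of the genes by length, against 4 of the 74 higher calls. With the trend removed, an alternative chosen after seeing the data, 156 genes were called, 67 higher and 89 lower, and 146 of them were among the 188. Of the 39 long lower genes 11 stayed called, and of the other 75 lower genes 71. Laminin genes are among the long genes affected: *lam-1*, *lam-2* and *lam-3* fell by 0.39, 0.47 and 0.47 on the log2 scale (edgeR adjusted p = 0.0186, 0.0143 and 0.0423, named after their values were seen). With the trend removed none passed (edgeR adjusted p = 0.317, 0.112 and 0.418), at log2 fold changes of -0.21, -0.30 and -0.23. Without MH-1 replicate 1 these were -0.42, -0.36 and -0.49, smaller for *lam-2* only.

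**Figure D4:**
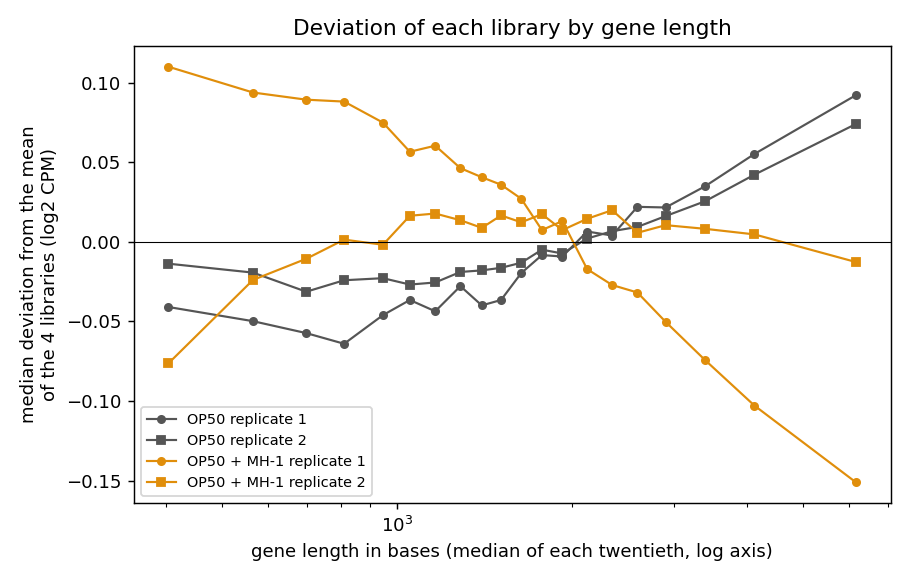
Median deviation of each library from the mean of the 4 libraries (log2 CPM, vertical axis) against gene length in bases (log axis), over 20 bins of the 5428 genes above 32 CPM, with OP50 in grey, OP50 + MH-1 in orange, circles for replicate 1 and squares for replicate 2. The line of OP50 + MH-1 replicate 1 falls with length, those of the OP50 libraries rise, and OP50 + MH-1 replicate 2 stays closer to 0 over most of the range. Deviations from a shared mean balance out, so part of the OP50 rise mirrors that fall.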

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

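The removal of the length trend and the thinning to equal depth were chosen after seeing the results, while the other alternatives were planned. None of the 188 called genes took the opposite sign in an alternative that tested it, and 3 were not tested with a filter of 1 CPM, 1 without OP50 replicate 1 and 1 after thinning. The counts stayed within 1.5 times of 188 with DESeq2 (171, of which 155 were shared), limma-voom (193), median-of-ratios (187) or total-count scaling (186), a filter of 1 CPM (186), non-robust dispersion (169), the length trend removed (156) and thinning (135). Without a filter on low counts 422 genes were called (138 higher, 284 lower), with all 188 among them, and the cause was not tested. A test against a fold of 1.5 left 23 genes (15 higher, 8 lower) and an adjusted p under 0.01 left 78 (43 higher, 35 lower), as a stricter criterion does. Leaving out a library, which makes the lone library of a group vary like the other group, gave 62 to 291 calls, 31 to 96 higher and 31 to 219 lower. The fewest were called without MH-1 replicate 1 (62) and the most without MH-1 replicate 2 (291), and the share of higher calls ran from 24.7% to 50% against 39.4%. Without MH-1 replicate 1, 52 of the 62 calls were among the 188.

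Lists called by camera numbered 12 to 20 over the alternatives against 15, and 0 with an estimated correlation (2 at an unadjusted p under 0.05) or with fry (8 at an unadjusted p under 0.05). The direction turned for fatty acid synthesis with limma-voom (adjusted p = 0.911) and in the list test of major sperm proteins without OP50 replicate 1 (adjusted p = 0.643, against 4.13e-13 without OP50 replicate 2), and the cause was not tested. Of 1360 gene values over the alternatives 112 called ones missed the threshold, 45 of them with a library left out, and 0 reversed. Of 586 list tests, 21 lost a call, the 2 that turned among them, and 29 gained one.

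With the replicate number as a replicate block, 271 genes were called (88 higher, 183 lower), with all 188 among them, 17 lists were called and no call of a named gene or list was lost. The numbers are not known to pair the libraries, and deviations of libraries with the same number correlated at -0.078 across genes. The 4 libraries can be split into pairs in 3 ways, too few for a share under 0.05. The real split gave 188 calls, the highest of the others 1, and 1 of the 3 splits gave as many as the real one. Depth limits the 2 shallower libraries, where 3 counts are about 0.2 CPM.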

Other observations

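Of the tests in this part, the annotation terms, the gene families, the neighbouring genes, the removal of the length trend, the sum over heat shock genes, the moulting genes taken in pairs, the tests of hypodermal share and the median of the NHR-49-dependent genes were chosen after the results had been seen. The lists of late embryonic and NHR-49-dependent genes were drawn up once the data had been seen, before the values of their other members were looked at. Among 4258 tests of annotation terms (hypergeometric, Benjamini-Hochberg), 4 terms were enriched among higher genes and 7 among lower genes. Defence against Gram-positive bacteria held 7 higher genes of 64 where 0.37 were expected (adjusted p = 1.39e-04), namely *lys-4*, *lys-5*, *clec-218*, *sodh-1*, *spp-1*, *spp-2* and *thn-2*. Innate immune response was enriched in both directions, with 12 higher (adjusted p = 1.57e-05) and 13 lower genes (adjusted p = 1.72e-04) of 225. The lysosome held 7 higher genes of 99 (adjusted p = 0.00144), among them the acid ceramidase gene *asah-1* (21.8 ± 0.0128 to 45.8 ± 9.11 CPM, SD, n = 2) and the sphingomyelinase gene *asm-2*. Copper ion transmembrane transport was enriched among lower genes through *F58G6.3*, *F58G6.7* and *F58G6.9*, 3 of 10 (hypergeometric adjusted p = 0.0406), which lie side by side on chromosome IV. The other copper terms among the 7 rested on these same 3 genes. Basement membrane genes were enriched among lower genes (5 of 28, adjusted p = 0.00346), and none of these 5 long genes (*lam-1*, *lam-2*, *lam-3*, *nid-1*, *tln-1*) was called with the length trend removed.

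Members of some small families were called too, without a test of any family. Of 15 tested saposin-like genes, which encode antimicrobial and lysosomal lipid-binding proteins, *spp-1*, *spp-2*, *spp-8* and *spp-18* rose, none fell and 11 did not pass, and both thaumatin-like genes (*thn-1*, *thn-2*) and both carotenoid oxygenase genes (*bcmo-1*, *bcmo-2*) rose. Of 6 *pud* genes, *pud-3* and *pud-4* fell. Of 15 *nspc* genes, *nspc-16*, *nspc-18* and *nspc-19* rose. Among 5 prolyl carboxypeptidase genes *pcp-1* rose and *pcp-2* fell. Some called genes were neighbours, 23 of the 188 in all. There were 12 pairs of adjacent tested genes called in the same direction, against a median of 1 and a highest of 8 in 10000 random placements of the calls over the tested genes (permutation p = 1.0e-04, the smallest these draws can give). Of these pairs 9 share a name root, such as *lys-4* with *lys-5*, and 3 do not, among them *fat-7* with *F10D2.10* (1356 bases apart on chromosome V) and *cth-1* with *argk-1* (1143 bases apart). In these last pairs both genes are on the same strand, and no explanation for the joint change was tested. The calls of *lys-5*, *asm-2*, *spp-1*, *spp-8*, *spp-18*, *thn-1*, *bcmo-1*, *bcmo-2*, *pcp-2*, *F58G6.7*, the 3 *nspc* genes and the 5 basement membrane genes were each lost without MH-1 replicate 1, some of them in other fits too. Every sign was kept there. The change was larger in that fit for *asm-2*, *spp-8*, *spp-18*, *thn-1*, *bcmo-2*, the *nspc* genes, *lam-1* and *lam-3*. It was smaller for *lys-5*, *spp-1*, *bcmo-1*, *pcp-2*, *F58G6.7*, *lam-2*, *nid-1* and *tln-1*.

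The fall of 5 inducible heat shock genes was tested against exchange of reads among near-identical copies. For this the counts of 9 genes were summed, these 5 and 4 that were not called. The sum pools Hsp70 family genes with *hsp-16* genes, so exchange within either family was not tested and may still set single values. The pooled sum fell by 0.73 on the log2 scale (95% interval -0.915 to -0.55), so exchange among the 9 genes did not make their joint fall. Nor did a single library set it, since the interval lay below 0 in 4 of 4 fits that leave out a library. Handling of the plates or worms at collection could also move these genes, and it cannot be told apart from diet because 0 of the labels give a collection time or batch. A lower basal heat shock response on MH-1 therefore remains a hypothesis.

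The fall of 8 cuticle collagens and 4 moulting genes was set against the length trend. With the trend removed, all 8 collagens stayed called (median log2 -0.65 before, -0.68 after). This could not test the trend for them, since they are short (median 1066.5 bases, against 1363 for all tested genes). Tested genes of similar length (median 969 bases) had a median log2 fold change of 0.0557, so at that length the trend ran upward. For *noah-1* and *noah-2* (3796 and 2566 bases), 2 of 2 stayed called (-0.50 ± 0.09 and -0.55 ± 0.105 SE after). That argues against the trend as the whole cause of the fall of *noah-1* and *noah-2*. For *fbn-1* and *mlt-11*, 0 of 2 stayed called and the trend cannot be told apart, since their folds shrank from -0.72 ± 0.12 and -0.75 ± 0.15 to -0.48 ± 0.11 and -0.50 ± 0.16 (SE), which ended the calls. A smaller share of hypodermal tissue, which would lower its transcripts alike, cannot be told apart, because the answer turns on the size of the loss. Against the shift of the 10 most abundant collagens (-0.12), 11 of 96 collagens differed, all 8 called ones among them. Against that of the hypodermis markers (-0.26), 7 differed, 3 of the 8 called ones below the shift and 4 others above it. The marker list itself holds cuticle collagens, such as *dpy-7*, *rol-6* and *sqt-3*. Both shifts therefore come at least in part from the genes under test. The shift of these markers is itself uncertain (camera adjusted p = 0.0437; adjusted p = 0.602 with an estimated correlation), with a median of -0.125 in DESeq2 and limma-voom, of -0.04 without OP50 replicate 1 (camera adjusted p = 0.533), of -0.18 without MH-1 replicate 2 (0.0882) and of -0.17 with the trend removed (0.229). Fewer late embryos among the worms would lower other late embryonic genes, and 9 of 11 lay below 0 (8 with the trend removed). Of the 11, edgeR, DESeq2 and limma-voom called 0, and 6 had an unadjusted p under 0.05 in edgeR. The list includes the hypodermis marker *che-14*, and its genes were not checked to be silent outside embryos. It therefore cannot tell fewer late embryos from a smaller share of hypodermal tissue. Larvae among the worms were not tested for, and a direct effect of diet on the cuticle stays open.

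The rise of *fat-7* was tested against exchange of reads with its close relative *fat-6*, and the summed counts still rose by 0.53 (log2; 95% interval 0.337 to 0.714). A single library did not set the sign of the rises of *fat-7*, *ech-1.1*, *cpt-5* and *lipl-2*, since 16 of 16 unadjusted intervals with a library left out lay above 0. This was a weak test, because the genes were picked among calls whose replicates do not overlap. The size of a rise did vary, for *lipl-2* from 0.89 (log2) without OP50 replicate 1 to 1.62 without OP50 replicate 2. Whether lipid genes that depend on the nuclear receptor NHR-49 rose in common was not decided. The test first planned, on the 9 members not seen before, left it undecided (5 of 9 above 0). All 13 listed genes, with *fat-7*, *ech-1.1*, *cpt-5* and *acs-2* included, had a median of 0.16 and an upper quartile of 0.37, and 9 lay above 0. Most of them thus stayed below *lipl-2* (1.26), the smallest of the 4 rises and not a listed gene. Those 4 were picked as large rises, so a smaller common rise remains possible. A role of NHR-49 at single genes and the diet itself, including its fatty acids, were not measured and stay open.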
